A study of Mus musculus with 13 samples.

How the data were processed

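The glucocorticoid receptor (GR, encoded by Nr3c1) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts. Per the labels' protocols, the cells came from male C57BL/6 embryos at embryonic day 13.5, were cultured for 7 days and were fixed with a protein crosslinker before formaldehyde. 1 commercial antibody against the receptor served for all libraries. The 13 libraries fell into 5 groups by the genotype and treatment in their labels. Under dexamethasone (Dex, a synthetic glucocorticoid; 1 µM for 16 h) with lipopolysaccharide (LPS, a bacterial cell wall component that sets off inflammatory signalling; 100 ng/µl for 3 h, as the labels give the dose), there were 3 wild-type, 4 mutant and 2 knockout libraries. Under Dex alone there were 2 wild-type and 2 mutant libraries. The mutant, labelled GR Zn/Zn, carries a change in a zinc finger of the receptor's DNA-binding domain.

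The deposited values were peak positions in base pairs and distances from peak to gene, with no count, score, height, fold enrichment, p-value or q-value of any peak. The submitters' processing notes name BWA 0.7.13, Picard 1.119 and MACS2 2.1.0 and the mouse build mm10, without saying which step each was used for. Per the file names, the Dex+LPS libraries were merged by genotype, peaks also found in knockout cells were removed, and the remainder was divided by the authors into wild-type-specific, shared and mutant-specific lists. In these lists each peak was exactly 200 bp wide. The Dex libraries had 1 list each, with a false discovery rate threshold in the file name, and widths from 202 to 3852 bp. How the merging, the control and the annotation were done is not given in the sources used here. The number of reads behind each list was not used here, so the depth is unknown. A list from more or deeper libraries can hold more peaks for that reason alone, and 4 merged mutant libraries stood against 3 merged wild-type libraries. Merging that keeps only peaks found in several libraries could act the other way, so the direction of such a bias is unknown.

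Each peak was taken with the gene and the signed distance to the gene start that the authors' annotation gives. Coordinates are 1-based in mm10. Of the Entrez gene identifiers, 99.9% (mutant-specific, shared and wild-type-specific lists) and 100% (Dex lists) matched a gene table of the same assembly (GRCm38). A few genes, Mir3084-1 among them, have spans of many megabases in the files and collected peaks from a whole stretch of chromosome.

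Peak sets were compared by overlap of at least 1 bp, checked against bedtools 2.31.1 on 500 random intervals, with the same answers. Shares are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Overlap by chance was taken from 1000 random circular shifts of the peaks along their chromosomes. Classes of Dex+LPS peaks were compared by Fisher's exact test (two-sided) across peaks, with Benjamini-Hochberg adjustment over the 21 tests of position. Such a test compares lists of peaks and not samples. Gene lists were tested by the number of their genes with at least 1 peak of a class. That number was set against 100000 random lists of the same size, drawn from 21454 genes and matched on the decile of gene territory (gene length plus part of the gaps to its neighbours). The random lists give two-sided permutation p-values of at least 2.00e-05, and Benjamini-Hochberg adjustment ran over the 42 pairs of 14 lists and 3 classes. On simulated lists of 30 genes, p was below 0.05 in 2.5% of unenriched lists for wild-type-specific, 2% for shared and 1.5% for mutant-specific peaks. With 25% of the simulated list placed on bound genes, the test called 39.5% of lists for wild-type-specific, 99% for shared and 100% for mutant-specific peaks, and with 50% it called 97%, 100% and 100%. The difference between the wild-type-specific and mutant-specific classes gave p below 0.05 in 4.5% of unenriched lists, and in 45% and 97% of lists with 25% and 50% of genes placed on mutant-specific peaks. A moderate enrichment at wild-type-specific peaks or between classes can thus be missed. Random and simulated lists drew genes independently, whereas some fixed lists hold neighbouring genes, so permutation p-values may be too small. The numbers and shares of the Dex libraries were compared by an exact permutation test of 2 against 2 libraries (two-sided), whose smallest possible p is 0.33. Nothing says that the Dex libraries came from separate cultures, so their spread may be technical. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

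The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were known GR targets, inflammatory genes of the NF-kB pathway, the AP-1 family, the circadian clock, the interferon response, extracellular matrix and fibroblast genes, adipogenesis and lipid genes, markers of macrophages, endothelium, muscle, neurons, epithelium and liver, and ribosomal and housekeeping genes. The rule named the genes with the 10 highest peak scores and the 5 genes with most peaks in each class. It also named up to 20 list genes by score among those with a mutant peak, the 10 highest Dex peaks found in both libraries of a genotype, known targets among these peaks, and Nr3c1. The plan assumed a peak score and a genome. With no score, genes were ranked by number of peaks (ties in alphabetical order, since all widths were equal) and Dex peaks by width. The planned comparison of peak strength, the stricter thresholds and the search for 16 DNA motifs were not run. Genes named outside the rule as examples were chosen after their values were seen. Alternatives were other distances to genes, a stricter overlap, autosomes and X only, each Dex library left out in turn, and the replicate number as a block. Added after seeing the data were analyses without chromosomes 10 to 14, genes assigned by the body that holds the peak, a 1 kb tolerance for shared peaks, the gene lists at Dex peaks, the difference between classes in the number of list genes (set against the same difference in random lists, since class sizes differ) and the share of a list's peaks that were shared.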

Results

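GR ChIP-seq peaks were compared between wild-type mouse embryonic fibroblasts and fibroblasts whose receptor carries a zinc finger mutation in its DNA-binding domain. The question was how much receptor binding remains in cells with this mutation; whether the mutant receptor still touches DNA was not measured here. Cells had received Dex with LPS (3 wild-type, 4 mutant and 2 knockout libraries) or Dex alone (2 wild-type and 2 mutant libraries). The Dex+LPS data were 3 merged lists from which peaks found in knockout cells had been removed, so they carry no spread between replicates. Dex alone had 1 peak list per library. The depth behind each list is unknown.

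Nr3c1, the gene of the receptor itself (chromosome 18, 39410545 to 39489776), had 3 wild-type-specific, 2 shared and 1 mutant-specific peak under Dex+LPS. A wild-type-specific peak lay inside the gene, 114 bp from its start (39489563 to 39489762), and the mutant-specific peak 728 bp upstream (39490405 to 39490604). No Dex library had a peak at Nr3c1. These positions give no level of the receptor, so they do not check the genotype labels.

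Under Dex+LPS most wild-type binding sites were missing from the mutant list. Wild-type cells had 22486 peaks and mutant cells 5720, 3.93 times fewer. The lists held 18953 wild-type-specific, 3533 shared and 2187 mutant-specific peaks. The mutant thus shared 15.7% of the wild-type peaks (95% interval 15.2 to 16.2%), and 61.8% of the mutant peaks were also wild-type peaks (60.5 to 63.0%). Peaks of the wild-type list were assigned to 8294 genes and those of the mutant list to 3194. Of the 1364 genes with a mutant-specific peak, 1022 (74.9%) also had a wild-type peak and 342 had none. The libraries are separate samples, but only merged peak lists were used here, so no test across samples was run.

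**Figure D1:**
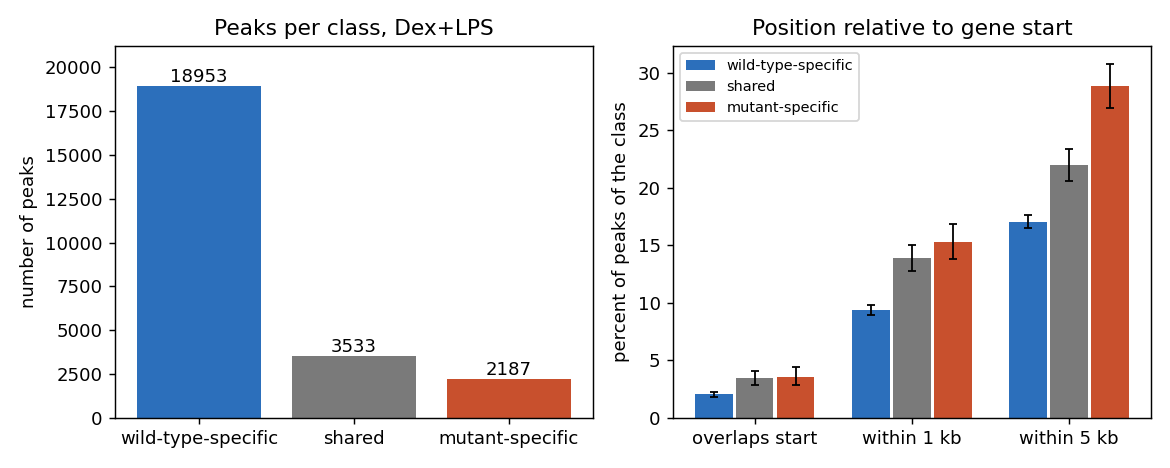
Number of Dex+LPS peaks in each class (left) and percent of the peaks of each class that overlap a gene start or lie within 1 kb or 5 kb of it (right, error bars are exact 95% binomial intervals). Wild-type-specific peaks were the most numerous (18953) and had the lowest share at gene starts at each distance.

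Known GR target genes were bound in both genotypes. Of 45 listed targets, 32 had a wild-type-specific peak, 17 a shared peak and 16 a mutant-specific peak. Fkbp5, a chaperone that restrains the receptor, had 15 wild-type-specific peaks, 1 shared and no mutant-specific peak. Dusp1, a phosphatase that switches off MAP kinases, had 11 wild-type-specific peaks and no mutant peak. Tsc22d3, which encodes the anti-inflammatory protein GILZ, had 5 wild-type-specific peaks and Zbtb16 had 7, again with no mutant peak. Tsc22d3 lies on the X chromosome, which held only 130 wild-type-specific, 15 shared and 14 mutant-specific peaks. Wild-type-specific peaks numbered 0.762 per Mb there, against 6.95 on chromosome 1, so a missing mutant peak at Tsc22d3 says little. In all, 15 of the 36 targets with a wild-type peak (41.7%) had no mutant peak, among them Klf9, Klf15, Lpin1 and Hif3a, against 65.6% of the 8294 genes with a wild-type peak; this difference was not tested. At other targets mutant peaks were as many or more. Errfi1, an inhibitor of EGF receptor signalling, had 4 wild-type-specific, 2 shared and 7 mutant-specific peaks. Tnfaip3, an inhibitor of NF-kB, had 4, 5 and 6, and the cell cycle inhibitor Cdkn1a had 0, 3 and 4. Acsl1, Mt2 and Pdk4 had mutant-specific peaks and no wild-type peak.

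The number of bound targets exceeded that of random lists in each class (permutation test, adjusted p = 6.46e-05, the smallest reached here, in each). Random lists had 17.2, 5.36 and 2.97 genes with a wild-type-specific, shared or mutant-specific peak, so the excess was 1.86-fold, 3.17-fold and 5.40-fold. The difference of 16 genes between the wild-type-specific and mutant-specific classes was not past the threshold against random lists (14.2; permutation test, adjusted p = 0.992 over 42 tests). Of the 150 wild-type peaks at these targets 21.3% were shared, against 15.7% at all other genes (Fisher's exact test, adjusted p = 0.165).

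The share of wild-type sites also found in the mutant was higher at inflammatory genes than at other genes. Of 136 wild-type peaks at the 38 NF-kB pathway genes, 47 were shared, 34.6% against 15.6% elsewhere (interval 26.6 to 43.2%; Fisher's exact test, adjusted p = 1.04e-06). Of the 38 genes, 27 had a wild-type-specific, 20 a shared and 15 a mutant-specific peak, 2.24, 5.54 and 7.28 times the mean of random lists (permutation test, adjusted p = 6.46e-05 in each class). The difference of 12 genes between the wild-type-specific and mutant-specific classes was not past the threshold against random lists (9.96; permutation test, adjusted p = 0.970). Il6, the gene of the cytokine interleukin-6 (chromosome 5, 30013114 to 30019981), had 3 wild-type-specific, 3 shared and 4 mutant-specific peaks, and a shared peak (30012998 to 30013197) overlapped its start. Csf1, a macrophage growth factor, had 12, 9 and 5 peaks in the same order. The adhesion molecule Vcam1 had 3, 4 and 8, and the NF-kB regulator Nfkbiz had 5, 4 and 5. Lif had 6 wild-type-specific and 5 shared peaks and no mutant-specific peak. By contrast 7 genes had wild-type peaks and no mutant peak assigned to them, namely the chemokines Ccl2, Cxcl2, Cxcl10 and Cxcl12, and Csf3, Mmp13 and Tlr4. Cxcl10 lies inside the body of Art3 (chromosome 5, 92331799 to 92414628), which held 4 mutant-specific, 4 shared and 3 wild-type-specific peaks. The missing mutant peak at Cxcl10 may therefore reflect the annotation. Icam1, Myd88 and Ripk2 had mutant-specific peaks and no wild-type peak. Ribosomal and housekeeping genes, the control for strong transcription, shared 29.0% of their wild-type peaks and AP-1 genes 27.0% (Fisher's exact test, adjusted p = 0.165 each). These lists had only 31 and 37 wild-type peaks and were not compared with the inflammatory list. The higher share is thus not shown to be particular to inflammatory genes. Peaks of 1 gene are not independent, so these tests across peaks overstate the precision.

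Interferon response genes were the list with the highest share of genes carrying mutant-specific peaks. Of 21 genes, 15 had a mutant-specific peak, against 0.864 in random lists, a 17.4-fold excess (permutation test, adjusted p = 6.46e-05). Some of these genes are neighbours, such as Mx1 and Mx2 or Oasl1 and Oasl2, and are not independent as random genes are. For wild-type-specific peaks the list was not past the threshold (6 genes against 4.88, permutation test, adjusted p = 0.901), and for shared peaks it did (6 against 1.36, adjusted p = 0.00566). Of its 19 wild-type peaks, 42.1% were shared, against 15.7% elsewhere (Fisher's exact test, adjusted p = 0.0254). Ifit2 alone gave 3 of the 8 shared peaks, so this test across peaks also overstates the precision. Mx2, an antiviral GTPase gene (chromosome 16, 97536081 to 97560901), had 12 mutant-specific peaks, all inside the gene, and 2 wild-type-specific peaks, of which 1 lay 657 bp upstream of its start. Ifih1, a sensor of viral RNA, had 11 mutant-specific peaks, 1 shared and no wild-type-specific peak. Gbp2 had 9 mutant-specific and 2 wild-type-specific peaks, and Cmpk2, Oasl2 and Usp18 had 4 mutant-specific peaks and 1 shared peak each. In all, 7 of the genes (Ifi44, Irf7, Mx1, Oas1a, Oasl1, Rsad2 and Stat2) had mutant-specific peaks and no wild-type peak assigned to them, and Ifit3, Ifnb1 and Isg15 the reverse. Ifit3 lies within a run of 8 mutant-specific peaks (chromosome 19, 34569833 to 34605742) that the annotation assigned to Ifit2, Ifit1bl1 and Mir3084-1. Mutant-specific peaks thus reached 9 more genes than wild-type-specific peaks, where in random lists the wild-type-specific class led by 4.03 genes (permutation test of the difference, adjusted p = 0.000420).

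**Figure D2:**
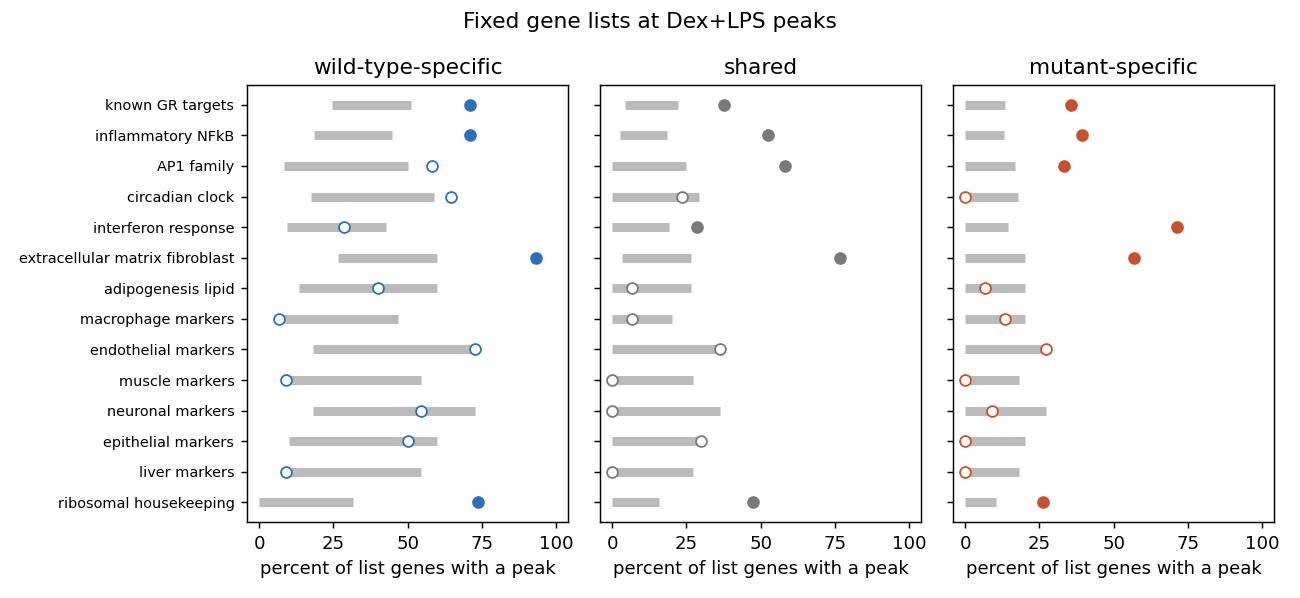
Percent of the genes of each of the 14 fixed lists that had at least 1 peak of each Dex+LPS class; grey bars span the central 95% of random lists matched on territory and filled points have an adjusted p under 0.05. The interferon response list reached 71.4% at mutant-specific peaks and 28.6% at wild-type-specific peaks.

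Of the remaining lists, extracellular matrix and fibroblast genes were bound in each class, with 28, 23 and 17 of 30 genes at wild-type-specific, shared and mutant-specific peaks (random lists 13.1, 4.28 and 2.36; permutation test, adjusted p = 6.46e-05 in each). Their wild-type peaks were shared in 27.2% of cases, against 15.6% elsewhere (Fisher's exact test, adjusted p = 9.36e-05). Tnc alone gave 13 of the 59 shared peaks, and peaks of 1 gene are not independent, so this test overstates the precision. Tnc, which encodes the matrix glycoprotein tenascin-C, had 22, 13 and 15 peaks in that order. Genes of the AP-1 family, transcription factors activated by stress and growth signals, were enriched at shared peaks (7 of 12, random lists 0.941, permutation test, adjusted p = 6.46e-05) and at mutant-specific peaks (4 of 12, random lists 0.574, adjusted p = 0.00829). At wild-type-specific peaks 7 of these genes were bound, with an adjusted p of 0.0612. Without chromosomes 10 to 14 the mutant-specific call of this list was lost (2 of 10 genes, 5.54-fold over random lists against 6.97-fold with all chromosomes; permutation test, adjusted p = 0.207). Circadian clock genes showed no mutant-specific peak in any of 17 genes, while 11 had a wild-type-specific peak. The difference between the classes did not pass (random lists 5.17; permutation test, adjusted p = 0.0697), and neither value passed against random lists (permutation test, adjusted p = 0.901 and 0.0515). Nr1d1, Nr1d2, Cry1, Cry2, Arntl, Npas2 and Hlf had wild-type peaks and no mutant peak.

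Ribosomal and housekeeping genes, included as a control for strongly transcribed genes, were enriched too. Of 19 such genes, 14, 9 and 5 had a wild-type-specific, shared or mutant-specific peak, against 3.08, 0.916 and 0.603 in random lists (permutation test, adjusted p = 6.46e-05, 6.46e-05 and 0.00168). Their wild-type-specific class led the mutant-specific one by 9 genes, against 2.47 in random lists (permutation test of the difference, adjusted p = 0.0182). A list enriched in both classes can show a larger lead than random lists do, because the wild-type-specific class is larger. The excess over random lists was 4.55-fold at wild-type-specific and 8.29-fold at mutant-specific peaks. These folds have unlike ceilings, as random lists already had 3.08 of 19 genes in the first class and 0.603 in the second. Neither the lead nor the folds thus decide whether these genes prefer a class. With genes taken by the body that holds the peak, 3 of the 19 were bound at shared peaks and that call was lost (permutation test, adjusted p = 0.0782). Random lists were matched on territory and not on transcription, so each enrichment given here includes any preference of peaks for active genes. Markers of macrophages, endothelium, muscle, neurons, epithelium and liver and the adipogenesis list passed the threshold in no class. Their lowest adjusted p was 0.213, for macrophage markers, of which 1 of 15 genes had a wild-type-specific peak.

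The genes with most peaks overlapped in part between classes, with Gm21119 named in each. In the wild-type-specific class they were Mir3084-1 (122 peaks), 1700001F09Rik (60), Gm21119 (43), Zfp982 (37), Pde4d (32), Tns3 (31) and Foxp1 (27). Among shared peaks they were Mir3084-1 (27), Gm21119 (18), Tnc (13), Zfp709 (12), Klf6 (11) and Tm4sf1 (10). Mutant-specific peaks were most frequent at A930037H05Rik (20), Tnc (15), Prl2c3 (14), 3110039I08Rik (13), Mx2 (12), Gm21119 (12), Ifih1 (11), Mir1932 (10), Fstl1 (9) and Gbp2 (9). Mir3084-1 is given a span of 24942235 to 60774397 on chromosome 19, and its count reflects that length. Peaks need not lie in the gene named. Inside the gene lay 7 of the 20 mutant-specific peaks assigned to A930037H05Rik and 0 of the 10 assigned to Mir1932. The same held for 3 of the 60 wild-type-specific peaks assigned to 1700001F09Rik.

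Mutant-specific and shared peaks lay closer to gene starts than wild-type-specific peaks did. A gene start was overlapped by 2.02% of wild-type-specific peaks (383 of 18953), 3.42% of shared (121 of 3533) and 3.57% of mutant-specific peaks (78 of 2187). Wild-type-specific peaks were lower than shared (Fisher's exact test, adjusted p = 3.51e-06) and than mutant-specific peaks (adjusted p = 2.68e-05), while the difference between the latter classes did not pass (adjusted p = 0.767). Within 5 kb of a start lay 17.1%, 22.0% and 28.9% of the peaks, and at this distance mutant-specific peaks also exceeded shared ones (Fisher's exact test, adjusted p = 2.06e-08). The median distance to the start was 42.3 kb for wild-type-specific, 37.2 kb for shared and 20.8 kb for mutant-specific peaks.

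Under Dex alone wild-type libraries had about 10 times as many peaks as mutant libraries. The wild-type libraries held 412 and 854 peaks (mean 633 ± 313, SD, n = 2) and the mutant libraries 53 and 60 (mean 56.5 ± 4.95, SD, n = 2). The mean difference was 3.39 on the log2 scale, 10.5-fold, and both wild-type libraries exceeded both mutant libraries (exact permutation p = 0.33, the smallest this design allows). Among known targets, Fkbp5, Per1, Zbtb16, Hif3a and Cdkn1a had a peak found in both wild-type libraries. The Fkbp5 peak lay 608 bp upstream of the gene start in library 1 (chromosome 17, 28517951 to 28518312). The peak at Per1, a clock gene, lay inside the gene (chromosome 11, 69096907 to 69097214). Lpin1 and Pdk4 had a peak in library 2 alone. Of the 45 targets, 5 and 7 were bound in the wild-type libraries, against 0.675 and 1.15 in random lists (permutation test, adjusted p = 0.0258 and 0.00784 over 56 tests, chosen after seeing the data). No target was bound in a mutant library, where random lists had 0.0847 and 0.103, so that absence carries no information.

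**Figure D3:**
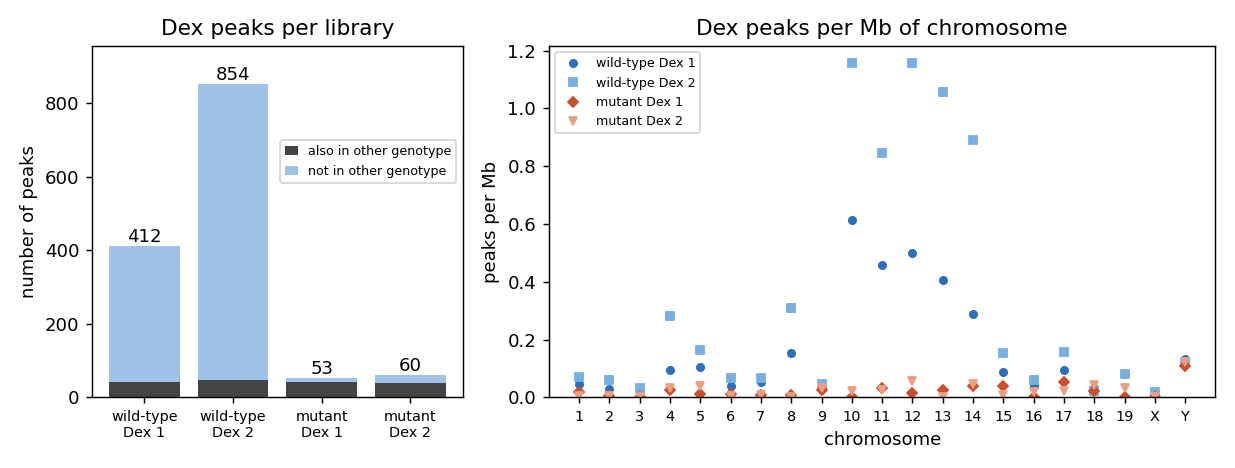
Number of Dex peaks per library, divided into those that overlap a peak of the other genotype and those that do not (left), and Dex peaks per Mb of each chromosome, 1 point per library (right). Wild-type libraries had 412 and 854 peaks, of which 281 and 631 lay on chromosomes 10 to 14, and mutant libraries 53 and 60.

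Chromosomes 10 to 14 held 68.2% (281 of 412) and 73.9% (631 of 854) of the wild-type Dex peaks, against 26.4% and 31.7% in the mutant libraries and 22.7% of the chromosome length. In the Dex+LPS lists they held 30.7% of wild-type-specific, 37.1% of shared and 39.9% of mutant-specific peaks, a smaller excess. Without these chromosomes the wild-type libraries had 131 and 223 peaks and the mutant libraries 39 and 41, a 4.27-fold difference (exact permutation p = 0.33). With peaks of the other genotype left out on all chromosomes, 370 and 806 wild-type peaks stood against 10 and 21 mutant peaks, a 37.7-fold difference. With both left out, a choice made after seeing the data, 99 and 185 wild-type peaks stood against 6 and 10 mutant peaks, 17.5-fold. Peaks of the other genotype were 42 and 48 in the wild-type and 43 and 39 in the mutant lists. Leaving them out removes most of the shorter lists, so the 37.7-fold and 17.5-fold values are larger by construction and add no evidence of lost binding.

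The few mutant Dex peaks were mostly also wild-type peaks. Of the mutant peaks, 43 of 53 (81.1%, interval 68.0 to 90.6%) and 39 of 60 (65.0%, interval 51.6 to 76.9%) overlapped a wild-type Dex peak, where shifted peaks gave at most 1. The reverse shares were 10.2% and 5.62%, and 24.4% and 17.0% without chromosomes 10 to 14. Between replicates, 44.7% of wild-type library 1 was found in library 2 and 21.3% of library 2 in library 1 (60.3% and 35.0% without chromosomes 10 to 14), and for the mutant 58.5% and 51.7%. Merged over the 4 libraries the peaks formed 1107 regions, of which 143 were found in both wild-type and no mutant library, 5 in both mutant and no wild-type library, and 20 in all 4. The widest peaks found in both libraries of either genotype were mainly assigned to Zfy1 on chromosome Y, 534219 to 655485 bp from its start, and to Gm5458 on chromosome 14, 185137 to 186517 bp from its start. In wild type they also included peaks assigned to Rab44, 6820431F20Rik, Gm21119 and Egfr, and in the mutant to Pitpnc1, Vmn2r-ps159 and Grid1 (868770 bp away). A 943 bp peak 61615 bp upstream of Egfr (chromosome 11, 16690117 to 16691059) was among the wild-type peaks.

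Dex peaks of wild-type cells recurred under Dex+LPS and those of mutant cells seldom did. Of the wild-type Dex peaks, 25.2% of 412 and 23.2% of 854 overlapped a Dex+LPS peak of any class, where shifted peaks gave means of 2.38 and 5.49 peaks. Without chromosomes 10 to 14 these shares were 24.4% of 131 and 15.2% of 223. In the mutant libraries it was 0 of 53 and 2 of 60 (3.33%); a count of 0 of 53 allows a share of up to 5.66% by the limit of 3 counts, and the exact 95% interval reaches 6.72%. The mean share was 24.2% ± 1.46 in wild type and 1.67% ± 2.36 in the mutant (SD, n = 2; exact permutation p = 0.33). By class, wild-type Dex peaks overlapped wild-type-specific peaks in 12.4% ± 2.42, shared peaks in 8.62% ± 1.55 and mutant-specific peaks in 3.76% ± 0.179 of cases (SD, n = 2 each). This split differed by chromosome. Of Dex peaks that overlapped any class, 47.2% and 42.1% on chromosomes 10 to 14 overlapped a wild-type-specific peak. Elsewhere it was 75% and 64.7% (Fisher's exact p = 0.0104 and 0.0225). Seen from Dex+LPS, 3.14% of shared, 2.01% of mutant-specific and 0.696% of wild-type-specific peaks overlapped a wild-type Dex peak, with chromosomes 10 to 14 included. At Per1 a shared peak (chromosome 11, 69096987 to 69097186) lay within the Dex peak of both wild-type libraries, and at Fkbp5 the Dex peak upstream of the start overlapped a wild-type-specific peak (chromosome 17, 28517911 to 28518110). The removal of knockout peaks applied to the Dex+LPS lists, and no such step is named for the Dex lists.

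**Figure D4:**
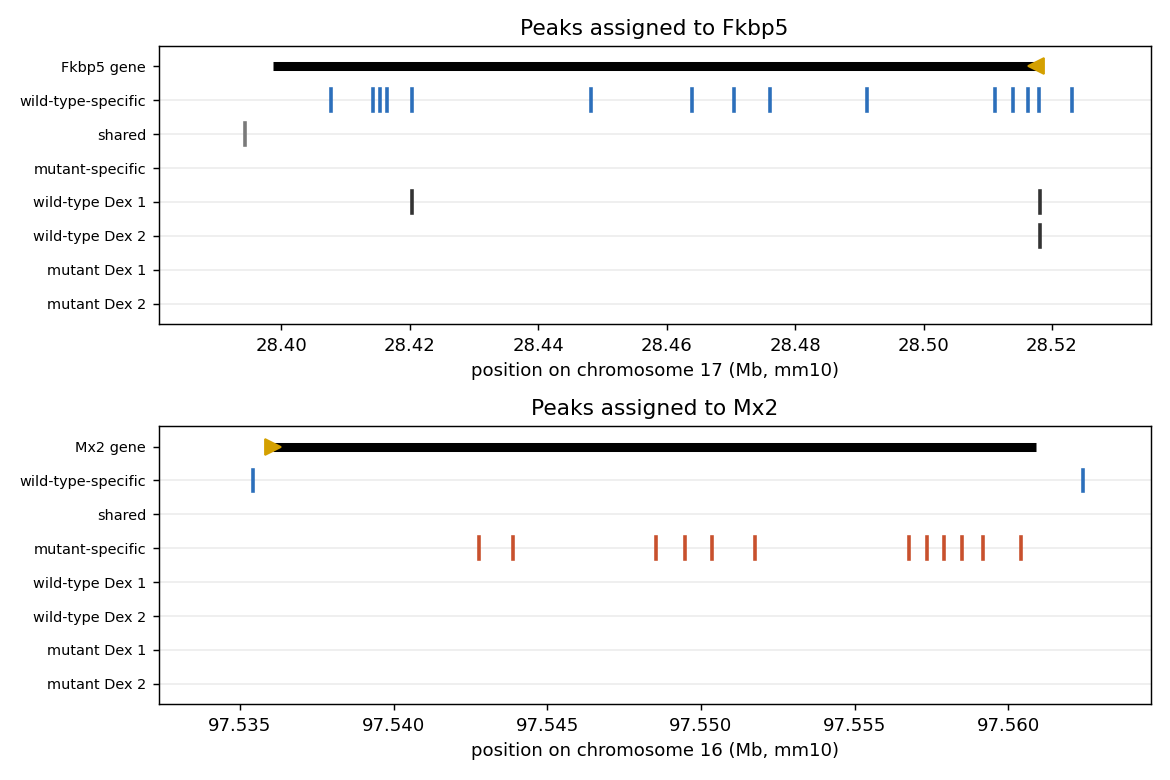
Peaks assigned to Fkbp5 (chromosome 17) and Mx2 (chromosome 16) in mm10 coordinates, 1 line of ticks per peak list, with the gene as a black bar and its start as a yellow arrow. Fkbp5 had 15 wild-type-specific and no mutant-specific peaks, and Mx2 had 2 wild-type-specific and 12 mutant-specific peaks.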

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

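Analyses without chromosomes 10 to 14, with a 1 kb tolerance or with genes assigned by gene body were chosen after the data were seen. The share of wild-type Dex+LPS peaks also bound in the mutant was 14.5% without chromosomes 10 to 14 and 18.9% when a mutant peak within 1 kb counted as shared. The difference of shared minus mutant-specific peaks near gene starts, not past the threshold for overlapped starts, was -6.89 percentage points within 5 kb and passed it; the cause was not tested. Without chromosomes 10 to 14 the overlaps of the wild-type Dex libraries were higher, for a reason not tested. Wild-type library 1 was then found in library 2 at 60.3%, in mutant library 1 at 16.8%, in mutant library 2 at 17.6% and in either mutant library at 24.4%. For wild-type library 2 these were 35.0% in library 1, 13.5%, 12.1% and 17.0%. With the replicate number as a block (a paired comparison of 2 pairs, smallest p 0.5) the Dex difference was 3.39 on the log2 scale (exact p = 0.5), 2.96 in pair 1 and 3.83 in pair 2. The numbers are not stated to pair the samples. Leaving out each library gave 2.87 to 3.92 and left an arm with 1 library, a value with no test. Gene list calls numbered 16 in the main analysis and 16 to 17 under the 4 alternatives, of which 15 or 16 were calls of the main analysis. The AP-1 family passed at wild-type-specific peaks within 100 kb (permutation test, adjusted p = 0.0481) and without chromosomes 10 to 14 (0.0385), and clock genes with gene bodies (0.0433). Of all values recomputed, 211 kept their direction and side of the threshold or moved by less than their interval, 10 moved further, 4 passed the threshold only under the alternative and 2 only in the main analysis. Another 20 changed from above to below random lists or the reverse, past the threshold in neither analysis. With gene bodies these were, at wild-type-specific peaks, 3 interferon genes (random lists 3.24), 3 adipogenesis genes, 1 neuronal and 1 epithelial marker. At shared peaks it was 1 macrophage marker, and at mutant-specific peaks 0 adipogenesis genes, 0 endothelial and 1 neuronal marker. Without chromosomes 10 to 14 they were 4 adipogenesis genes at wild-type-specific and 0 at mutant-specific peaks, 1 macrophage marker at shared and 1 neuronal marker at mutant-specific peaks. Within 10 kb they were 0 neuronal and 0 epithelial markers at wild-type-specific peaks, 0 endothelial and 0 epithelial at shared, and 0 adipogenesis genes and 0 endothelial markers at mutant-specific peaks. Within 100 kb they were 0 adipogenesis genes and 1 neuronal marker at mutant-specific peaks. The Dex tests cannot reach the threshold, so their stability says nothing of significance. Not run, for want of a score or a genome, were the stricter thresholds and score-based filters, peak strength, and all motif shares with their windows and mismatches. The unknown depth limits each count of peaks: a site missing from a list may be bound below its threshold.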

Other observations

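The gene families in this paragraph were chosen after their peaks had been seen, so their counts are given beside the mean of random lists and without a test. Immunity-related GTPases, which attack the vacuoles of intracellular parasites, had mutant-specific peaks in 7 of 8 genes (random lists 0.392). Guanylate-binding proteins, of which Gbp2 was also on the fixed interferon list, had them in 8 of 11 genes (0.511) and the Slfn family in 5 of 8 (0.322). At wild-type-specific peaks the same families had 2, 4 and 2 genes (random lists 2.19, 3.22 and 2.03). Class I histocompatibility and antigen processing genes had mutant-specific peaks in 7 of 39 genes (1.54), and the Parp9 to Parp14 family in 3 of 5 (0.254) with no wild-type peak. Core histone genes had 18 of 72 genes at wild-type-specific peaks (9.29), 20 at shared (3.15) and 6 at mutant-specific peaks (2.16).

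Mutant-specific peaks also stood in dense runs. Of these peaks 15.3% lay in clusters of at least 5 peaks with gaps up to 20 kb (interval 13.8 to 16.9%), against 3.11% of shared and 11.2% of wild-type-specific peaks, although a class with more peaks forms clusters more readily. The largest mutant-specific cluster held 31 peaks on chromosome 11 (119390345 to 119492285), of which 28 lay inside the body of Rnf213, a large ubiquitin ligase gene. The annotation of the files assigned them to Mir1932, A930037H05Rik and Endov. Only 2 wild-type-specific peaks lay in that body. Igfbp5 had 8 mutant-specific peaks in its body and no wild-type peak there, Parp14 9 and Tor3a 9.

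Of the tests in the paragraphs that follow, those on the excess on chromosomes 10 to 14, on wild-type signal below the threshold and on the recurrence of mutant Dex peaks were chosen after the results had been seen, as were the draws of whole genes. The first pattern is the mutant-specific binding at interferon response genes. Of 63 such peaks, 66.7% lay inside the gene more than 1 kb from its start, against 37.7% of the other mutant-specific peaks (Fisher's exact test, p = 5.21e-06; 0.0440 when whole genes were drawn at random), but by gene it was 9 of 15 against 38.9% (Fisher's exact p = 0.113). A candidate explanation is therefore signal spread along the bodies of strongly transcribed genes. Peaks also found in knockout cells under Dex+LPS had been removed, however, so such spread would have to be weaker or missing in the knockout. Of the 15 genes, only 5 had over 50% of their peaks inside the gene and over 1 kb from its start. Mx2, Gbp2, Ifih1 and Mx1 hold most of the peaks so placed. Only 1.59% had a wild-type peak within 1 kb, against 19.9% of the others (Fisher's exact p = 2.96e-05; 0.0285 with whole genes; by gene 1 of 15 against 24.8%, p = 0.136), so wild-type peaks just beside the interval are argued against for most of these peaks. Binding at the gene starts could not be settled (6.35% against 15.5%, Fisher's exact p = 0.0491, but 0.246 with whole genes), nor wild-type binding below the threshold (permutation test of wild-type-specific peaks at these genes, adjusted p = 0.901), and a difference between genotypes in interferon transcription stays open, as no expression was analysed here.

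The second pattern is the excess of wild-type Dex peaks on chromosomes 10 to 14. Regions called in every library are argued against, since mutant libraries had 26.4% and 31.7% of their peaks there and wild-type libraries 68.2% and 73.9% (Fisher's exact test, largest p of the 4 pairs = 9.59e-08). Receptor sites concentrated there are argued against as the whole cause, since wild-type-specific Dex+LPS peaks had 30.7% on these chromosomes (Fisher's exact test, larger p = 1.24e-53). That test left out the other classes, and shared peaks reached 37.1% and mutant-specific peaks 39.9%. Each Dex+LPS class thus also exceeded the 22.7% of chromosome length, so a smaller excess is not confined to wild-type Dex peaks. Calls at random positions are argued against as the whole cause. Of the peaks on these chromosomes, 37.4% and 16.5% recurred in the other wild-type library, where shifted peaks gave 0.0630% and 0.0296%. Background at the same positions in both libraries would recur too and is not excluded. Of peaks found in both wild-type and no mutant library, 66.9% and 66.7% lay on these chromosomes, against 22.7% of the chromosome length (exact binomial test, larger p = 3.27e-29). That share follows from the excess itself, so this test cannot decide on its cause. Weak background peaks as part of the excess cannot be told apart from real ones: of peaks absent from the mutant, 35.8% and 15.5% recurred in the other wild-type library, against 48.5% and 25.9% elsewhere (Fisher's exact test, larger p = 0.0306), while the same peaks overlapped Dex+LPS peaks in 26.6% and 26.4% of cases, against 32.3% and 18.4% elsewhere (Fisher's exact p = 0.297 and 0.0255); extra copies of these chromosomes, or a control with fewer reads on them, were not tested.

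The third pattern is that mutant Dex peaks recurred in wild type. At least 65.0% of each mutant library overlapped a wild-type peak, and 10 and 11 lay on chromosome Y. Of the wild-type Dex peaks that overlapped a mutant peak, 0 of 42 and 0 of 48 were found under Dex+LPS, where knockout peaks had been removed, against 28.1% and 24.6% of the others (Fisher's exact test, larger p = 3.69e-06; upper limits 8.41% and 7.40%). These are largely the regions of the mutant peaks, whose absence under Dex+LPS the report gives, so this test adds no independent evidence. Regions enriched without receptor binding to DNA cannot be told apart from receptor binding in both genotypes, as no knockout library under Dex alone was used here.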
